A study of Rattus norvegicus with 6 samples.

How the data were processed

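RNA was measured by sequencing in the cortex of 6 rat embryos at embryonic day 18, 3 of the Sprague-Dawley strain (SD) and 3 of the tish line, and per the labels each library came from 1 animal. The authors deposited 1 table of raw read counts per Ensembl gene ID, with 1 column per library. Per the submitters' processing notes, reads were aligned with STAR to the rat build Rnor_6.0 and counted with featureCounts 1.5.0. The STAR version, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so the counts of overlapping genes and near-identical copies are uncertain. The deposited values are whole numbers whose totals differ between libraries, so they were treated as counts with no normalization.

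The deposited table holds the same genes 2 times. Its first part has 32751 gene IDs and its second part 32754, and 0 values differ between the parts. The 3 IDs found only in the second part have 0 counts, and the line between the parts names no gene and holds 0 counts. Each ID was used once, which left 32754 IDs. All 6 columns were assigned to samples by the library name in the sample titles.

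Gene IDs were taken as the file gives them. The file does not pair them with symbols, and the reference table, which lists 47357 genes of the assembly GRCr8, gave an Ensembl ID for 0 of them, so 0 gene IDs received a symbol. The tests that had been planned on gene symbols or positions, including the check of the deleted gene Eml1 and the comparison of gene lists, were not analysed here. For the same reason the planned rule for printed genes, which asked for a symbol, was reduced after the file was seen: the 2 IDs with the largest log2 fold change in each direction, among genes with an adjusted p under 0.05, a mean of at least 1 CPM (counts scaled to a common library total) in the higher group and no overlap of the groups, are printed.

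Differences between tish and SD were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, libraries were scaled by TMM, and a quasi-likelihood F test (robust glmQLFit, glmQLFTest) was run with genotype as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Principal components and library correlations used log2 CPM with a prior count of 2. The sexes, 4 males and 2 females, were compared in the same kind of model with genotype as a second term. This comparison was set up after the file was seen, since the planned one needed named Y-linked genes.

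Library totals ran from 15625915 to 20844504 counts. A floor of 3 counts, the upper limit that a count of 0 allows, corresponds to 0.144 to 0.192 CPM in a library. A fold against a group at 0 compared the summed counts of the other group with 3 counts in each library of the group at 0. It was adjusted for summed library totals scaled by TMM, not taken from the mean CPM. Ratios of low counts carry exact 95% intervals, which together with the floors cover counting error only. Replicates were compared before averaging, and the chi-square statistic of each pair of libraries of 1 group was at least 8.56 times its degrees of freedom, over genes with at least 20 counts in the pair, so no library was counted as a repeat of another.

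The procedure was tested on simulated counts for the 14818 tested genes with 200 genes changed by known folds. It called 22 of 50 genes changed 1.5-fold, 31 of 50 changed 2-fold, 49 of 50 changed 4-fold and 45 of 50 changed 8-fold, and 12 of 14618 unchanged genes. With no gene changed it called 2. Far fewer genes were changed than the 3894 called in the data, and each gene was drawn independently. These rates therefore need not hold for the real comparison.

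The main test of tish against SD and the alternatives to it were set before the data were examined, as was the rule for printed genes apart from the reduction given above. The alternatives were DESeq2 1.42.0, voom in limma 3.58.1, RLE, upper quartile or no scaling factors, other count filters, sex as a covariate, males alone, each library left out in turn, adjusted p thresholds of 0.01 and 0.1, and glmTreat against a fold of 1.5. Added after the data were seen were the file as deposited, the removal of SD 1 and tish 3 together, thinning of every library to the smallest total, and the comparison of the sexes with its alternatives. Replicate numbers are names in the order of the samples and pair no animals across the groups.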

Results

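Gene expression was measured by RNA sequencing in the cortex of rat embryos at embryonic day 18. The tish rat (telencephalic internal structural heterotopia) is a line with a band of misplaced neurons beneath the normally placed cortex in both hemispheres, and the title of the series names a deletion in Eml1, which encodes a microtubule-associated protein. SD, the Sprague-Dawley rat, was the control. Each group had 3 animals, 2 males and 1 female. The dissected tissue differed in its description: the protocol names neocortex for SD, and for tish the cortex with its normally placed and heterotopic parts, while the labels of single samples read cortex for SD and neocortex for tish. Genotype and tissue description therefore changed together between the groups. Dam and litter were not among the sample descriptions used here. Whether the embryos of a group are independent replicates is therefore not known, and litter cannot be told apart from genotype.

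Total counts were 16939100, 18754337 and 18461168 in SD 1, SD 2 and SD 3, and 15625915, 20844504 and 20280487 in tish 1, tish 2 and tish 3. Between 18985 and 19364 genes had at least 1 count in a library, and the 10 most abundant genes took 4.04% to 4.73% of the counts. TMM factors lay between 0.970 and 1.04.

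The libraries separated by genotype. Over tested genes, Pearson's r of log2 CPM was 0.983 to 0.988 between libraries of SD, 0.981 to 0.989 between libraries of tish, and 0.955 to 0.967 between a library of SD and one of tish. These correlations are across genes, which are not independent replicates. The first principal component held 60.2% of the variance, with SD libraries at scores of -44.4 to -28.9 and tish libraries at 33.4 to 40.8. The second held 14.6% and did not part the genotypes.

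**Figure D1:**
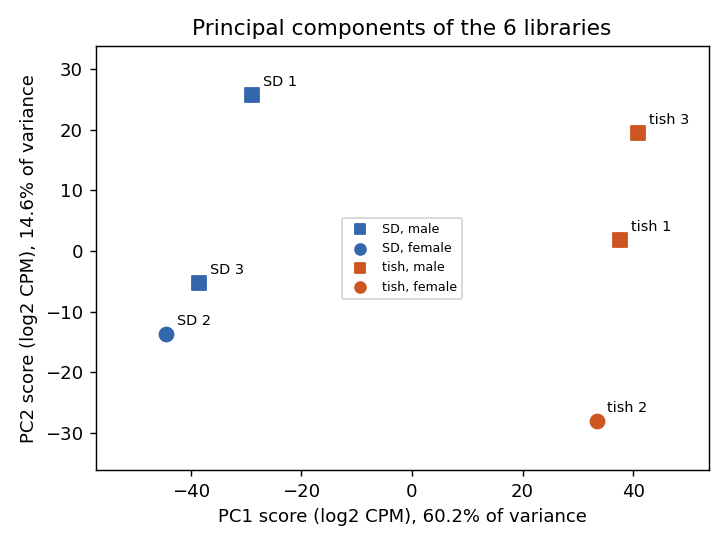
Scores of the 6 libraries on the first (x axis) and second (y axis) principal components of log2 CPM. Each point is 1 library, coloured by genotype with squares for males and circles for females. The 3 tish libraries lie at 33.4 to 40.8 on the first component and the 3 SD libraries at -44.4 to -28.9.

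The comparison of tish with SD asks which genes differ in expression in the cortex of the mutant line before birth. Of 14818 genes tested, 3894 (26.3%) differed, 1980 of them higher and 1914 lower in tish (edgeR quasi-likelihood test, adjusted p under 0.05). The changes were mostly modest, with a median absolute log2 fold change of 0.69, a fold of 1.61, among called genes. Of the called genes, 592 were more than 2-fold higher and 557 more than 2-fold lower in tish, 97 and 89 more than 4-fold, and 17 and 37 more than 8-fold. The 2 groups did not overlap in 3875 of the called genes. Over all tested genes they did not overlap in 6570 (44.3%), where a random split gives 10% on average. Genes that vary together can move this share far from 10% in a single split, so the comparison is no test of genotype. The median log2 fold change of all tested genes was -0.02. This median and the near-even split of calls depend on the scaling. Without scaling factors the median was -0.0535 and 43.3% of calls were higher in tish.

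Genes higher in tish took a larger part of the transcriptome there. The 1980 called genes higher in tish held 15.7% ± 0.891 of counts in SD and 22.5% ± 0.640 in tish (standard deviation, n = 3 each). The 1914 genes lower in tish held 14.3% ± 0.885 in SD and 9.54% ± 0.336 in tish (standard deviation, n = 3 each). These sets were chosen for their difference, so the shares give its size and do not test it.

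**Figure D2:**
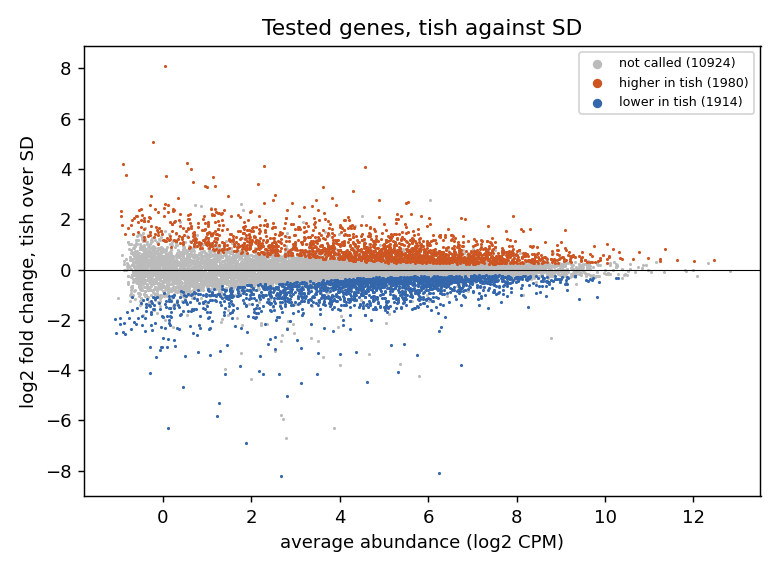
Log2 fold change of tish over SD (y axis) against average abundance in log2 CPM (x axis) for the 14818 tested genes. Each point is 1 gene, in orange where called higher in tish (1980), in blue where called lower (1914) and in grey where not called.

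Calls were fewest among genes of low abundance. When tested genes were divided into 5 equal classes by edgeR's average abundance, which includes a prior count, 16.9% of genes were called in the lowest class (0.471 to 3.57 on the CPM scale) and 26.4%, 28.8%, 29.0% and 30.4% in the next 4. The median absolute log2 fold change of called genes fell with abundance, from 1.39 in the lowest class to 0.45 in the highest (87.1 to 7240). Genes with low counts have larger standard errors and need a larger fold to be called. The fall therefore does not show that rarer transcripts changed more. Genes higher in tish made up 58.8% of calls in the highest class and 44.3% in the middle class.

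A few genes were near silent in 1 genotype. In tish, 3 genes had at most 3 counts over the group while the other group averaged at least 1 CPM, and in SD there were 2. All of them were called. The file does not pair IDs with gene symbols, so the genes with the largest changes are given by ID.

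The 2 printed genes that fell differed from SD by far more than the spread between replicates. ENSRNOG00000029286 had 2134, 3697 and 2495 counts in SD 1, SD 2 and SD 3 and 3, 20 and 8 in tish 1, tish 2 and tish 3. Its level was 152 ± 41.9 CPM in SD and 0.523 ± 0.403 CPM in tish (standard deviation, n = 3 each), a log2 fold change of -8.09 (SE 0.40, adjusted p = 0.0001). ENSRNOG00000020536 had 165, 354 and 167 counts in SD and 0, 2 and 0 in tish, a log2 fold change of -8.20 (SE 0.66, adjusted p = 0.000193). Its level in SD was 12.5 ± 5.74 CPM (standard deviation, n = 3), and the ratio of SD to tish counts, adjusted for library size, was 350 with an exact 95% interval of 96.6 to 2898.

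The 2 printed genes that rose were expressed at low level. ENSRNOG00000053494 had 0 counts in each SD library and 29, 61 and 13 in tish 1, tish 2 and tish 3, which is at least 11.2-fold higher in tish against a floor of 3 counts per SD library (edgeR adjusted p = 0.00876). Of its 103 counts in tish, 61 were in tish 2, so this fold rests largely on that library. The exact 95% interval for the ratio of its tish to SD counts began at 26.85, with no upper bound. That interval covers counting error only and is the measure given for ENSRNOG00000024181 below, unlike the fold against the floor. Without tish 1 the adjusted p was 0.0529, the highest of the alternatives, which ran from 6.54e-07 to 0.0529. ENSRNOG00000024181 had 0, 0 and 2 counts in SD and 19, 52 and 11 in tish, a ratio of 40.1 with an exact 95% interval of 10.8 to 337 (adjusted p = 0.00662). The fitted log2 fold change of ENSRNOG00000053494, with SD at 0 counts, rests on a prior count in edgeR and limma-voom and is no bound. It was 8.08 in edgeR with all libraries, 7.48 in edgeR without tish 2 and 5.84 in limma-voom. Without tish 2 the fitted log2 fold changes were 4.33 for ENSRNOG00000024181 (5.07 with all libraries), -10.81 for ENSRNOG00000020536 and -8.90 for ENSRNOG00000029286, and without SD 3 that of ENSRNOG00000024181 was 7.74. The same limit holds where a removal leaves a group at 0 counts, as for ENSRNOG00000020536 without tish 2 and ENSRNOG00000024181 without SD 3. A stricter filter of at least 1 CPM in 3 libraries removed both genes that rose from the test. Their identity is not analysed here, and reads shared with overlapping or near-identical genes are an open limit for all 4.

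The number of called genes depended on the libraries used. Without tish 1 it was 2437 and without tish 3 it was 2502, with 1130 and 1172 genes lower in tish. Without SD 1 it rose to 4764, with 2480 genes higher and 2284 lower in tish. Without tish 1 the genes higher in tish numbered 1307, and without SD 3 the genes lower in tish numbered 1262. With males alone, 2 against 2, 2130 genes were called. A fold above 1.5 was called for 732 genes, 389 higher and 343 lower in tish.

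Each group held 1 library that stood apart from its replicates in a small set of genes. SD 1 also differed more widely, over all genes with at least 20 counts in a pair. Its chi-square was 24.5 times the degrees of freedom with SD 2 and 21.6 with SD 3, against 14.6 between SD 2 and SD 3. Within tish it was 15.4 between tish 2 and tish 3, against 8.59 between tish 1 and tish 2 and 8.56 between tish 1 and tish 3. By Pearson's r, tish 2 and tish 3 were the least alike pair within a group, at 0.981. In tish 3, 46 genes lay at least 4-fold below every other library, against 0 to 6 genes in each of the others. These 46 genes took 0.0191% of the counts of tish 3 and 0.135% to 0.206% of the counts elsewhere, and 0 of them were called between genotypes. In SD 1, 18 genes lay at least 4-fold above every other library, against 0 in each of the others, and took 0.113% of its counts against 0.00313% to 0.0146% elsewhere. Of these, 1 was called. Genes chosen for 1 outlying library have a wide spread within its group, which makes a genotype call unlikely. The few calls in both sets therefore do not show that these libraries left the calls untouched. With SD 1 and tish 3 left out together, an alternative chosen after seeing the data, 3743 genes were called, 1945 higher and 1798 lower in tish. Of the 3894 genes called with all libraries, 3094 were among them in the same direction.

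**Figure D3:**
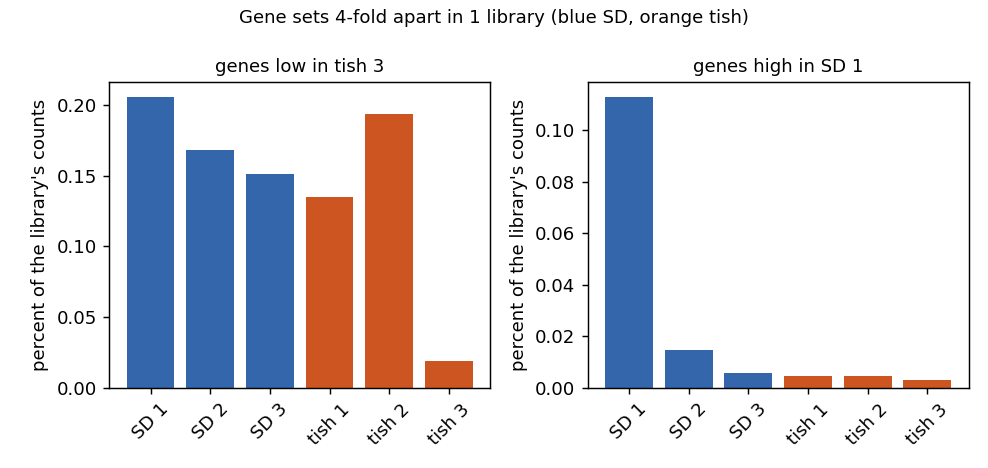
Percent of each library's counts (y axis) held by the 46 genes at least 4-fold lower in tish 3 than in every other library (left) and the 18 genes at least 4-fold higher in SD 1 (right). Each bar is 1 library, blue for SD and orange for tish. The sets were chosen for these differences, and tish 3 stands at 0.0191% on the left and SD 1 at 0.113% on the right.

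Sex was examined through genes chosen by the labels themselves, since gene symbols were not used here. By that choice, 5 genes had 0 counts in both libraries labelled female and at least 1 CPM in each of the 4 labelled male, where they summed to 2745 to 3692 counts. The same criterion for each of the 14 other pairs of libraries, added after the data were seen, gave 0 genes. With genotype in the model, 6 genes differed between males and females (edgeR adjusted p under 0.05). The same 5 were higher in males, and 1 gene was lower in males by a log2 fold change of -4.06, with at least 127 counts in each female library and at most 10 in each male library. DESeq2 called 22 genes between the sexes, and edgeR called 13 with no filter on low counts and 26 without SD 3. The interaction of sex and genotype is not interpreted, since that comparison has 1 female per genotype.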

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

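The alternatives with SD 1 and tish 3 left out, with thinning, with the file as deposited and for the sexes were chosen after seeing the data; the others were set before. Of 63 counts of genes under another setting, higher, lower or together, 45 stayed within 1.5 times the reported one. The total was 3839 to 4372 under DESeq2, voom, other scalings, other filters or sex as a covariate, 5203 at an adjusted p under 0.1, and 3817 after thinning. Without scaling factors 43.3% of calls were higher in tish, against 50.9%.

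Moved further were males alone (2130 genes, 1170 higher and 960 lower) and an adjusted p under 0.01 (1930, 1046 and 884). A fold above 1.5 (732, 389 and 343) and the file as deposited (7790, 3962 and 3828), in which each gene counts 2 times, also moved further. Males alone left 2 libraries per group and kept SD 1 and tish 3. Leaving out SD 1 and tish 3 also left 2 per group, yet called 3743 genes. Fewer samples alone therefore do not account for the count with males alone. With 1 library left out, totals ran from 2437 (without tish 1) to 4764 (without SD 1), genes higher in tish from 1307 to 2480 and genes lower from 1130 to 2284. Without tish 3 they were 2502, 1330 and 1172, and without SD 3 the lower genes were 1262. Genes differing between the sexes were 6, 13 with no filter, 22 with DESeq2, and 6 to 26 with 1 library left out, 26 without SD 3. The cause was not tested for the sexes, nor for which libraries moved the counts.

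For the 4 printed genes, 64 of 65 values kept direction and side of the threshold, 1 did not (ENSRNOG00000053494 without tish 1, adjusted p 0.0529) and 0 reversed. The filter of 1 CPM in 3 libraries left no value for the 2 genes that rose, males alone left none for ENSRNOG00000024181, which then missed the count filter, and the test against 1.5-fold was not used for single genes. Alternatives on gene symbols, lists and positions were not run, since no ID had a symbol. Depth limits genes of low abundance, since a count of 0 allows up to 0.144 to 0.192 CPM in a library. No paired analysis was possible because replicate numbers come from the order of the samples.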

Other observations

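All tests in this part were chosen after the results they concern had been seen. The first pattern is the number of genes that differ between tish and SD. The 6 libraries can be split into 3 and 3 in 10 ways, and 1 of them, the real one, called as many as 3894 genes, while the highest of the others called 0. With 10 splits a share under 0.05 cannot be reached. Every other split also mixes SD and tish in both of its groups, so the genotype difference widens the spread within them and lowers the calls. Their 0 calls are therefore no estimate of what chance alone would call. Unequal depth is argued against by thinning every library to the smallest total, after which 3817 genes were called. A difference in the tissue dissected cannot be told apart from genotype, because the groups share 0 tissue labels.

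The second pattern is the set of 46 genes that is low in tish 3, with a median 7.12-fold below the mean of the other 5 libraries. Shallower sequencing is argued against by the total of tish 3, which was 1.12 times the mean of the others. If the set came from 1 source of RNA present in unequal amounts, its genes would also move together between tish 1 and tish 2, and 100% of them were higher in tish 2, against at most 78.3% in 10000 random lists matched on expression. The 18 genes high in SD 1 were likewise all higher in SD 2 than in SD 3, against at most 94.4% in random lists. The lists were matched on expression alone, so any genes that vary together between animals would pass. The test therefore cannot tell a tissue or cell population taken along in a different amount from other shared variation, and no such source was identified. The 3 tish libraries share 1 genotype label, and no biological explanation was tested.

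The third pattern is a set of 3 genes with at least 5 CPM in each SD library, under 2% of the SD mean in tish 1 and tish 2, and over 10% of it in tish 3. The most abundant had 764 ± 132 CPM in SD (standard deviation, n = 3) and 0.383, 0.194 and 346 CPM in tish 1, tish 2 and tish 3. None of the 3 was called between genotypes (edgeR adjusted p 0.155 to 0.457), which their choice for a difference within tish made likely. SD RNA mixed into tish 3 is argued against by the 2 other genes near absent from tish 1 and tish 2, which stayed at 0 and 0.268% of SD in tish 3. An allele missing from tish 1 and tish 2 and carried once by tish 3 may give a level near 50% of SD, while the 3 genes stood at 45.3%, 28.1% and 39.3%, a median of 39.3%, which without genotypes of the animals stays open. Reads of 1 abundant gene shared with near-identical copies also stay open, since the ratio to the most abundant gene varied by a CV of 7.67% to 21.3%. With limits of 5% and 20% in place of 2% and 10%, 5 genes showed the pattern.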
